A study of Homo sapiens with 8 samples.

How the data were processed

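Total RNA of the human lung adenocarcinoma lines NCI-H1299 and NCI-H2009, here H1299 and H2009, was measured on 8 Affymetrix arrays with a single biotin label. Per the labels' protocols, cells were infected with lentivirus carrying a short hairpin RNA for 2 days, selected with puromycin for 2 days, and harvested at day 4 after infection. Each line received 2 hairpins against PTK7, here PTK7-1 and PTK7-2, and 2 control hairpins, against GFP and luciferase (LUC), with 1 array per hairpin and line. The arrays therefore form 4 groups of 2, and the 2 arrays of a group carry different hairpins. Nothing in the labels says whether cultures were repeated, so p-values measure the spread between these arrays. The labels give no batch, and the hairpin sequences were not used here.

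The deposited values are log2 expression values per probe set, made by the authors with RMA in R 2.14.0, per the submitters' processing notes. RMA corrects the background, normalizes between arrays and summarises the probes of a probe set. Array medians lay between 5.31 and 5.41, and no pair of arrays held identical values. The arrays held 32321 probe sets. Pearson r within a group, across the 18404 genes kept as described below, ran from 0.981 to 0.997. The number of arrays limits the precision, and detection calls were not used here. In the annotation table of the array, 19158 probe sets had a single gene symbol, 1388 had several and 11775 were not listed. Of the single symbols, 19128 were matched by gene ID to the current gene table and 0 needed an update. The probe set with the highest mean was kept for each of 637 genes with several, which left 18404 genes. The scale is that of RMA, where small differences of dim genes are compressed.

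Groups were compared with limma 3.58.1 in R 4.3.3, with a mean per group over all 8 arrays, empirical Bayes moderation and Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. Contrasts were the PTK7 minus control difference averaged over the lines, the same in each line, the H1299 minus H2009 difference of these, and the H1299 minus H2009 difference under control hairpins. The 2 PTK7 hairpins, and the 2 control hairpins, were compared in a fit of hairpin plus line. Errors given after ± are standard errors of the fit unless marked SD. The same hairpins were used in both lines, as the labels state, and arrays with the same hairpin deviated together from their group means, with r between the lines of 0.230 for the control hairpins and 0.407 for the PTK7 hairpins. A fit with the hairpin as a block was therefore run beside the one without it. The blocked fit removes what each hairpin does in both lines from the error and so refers to these 4 hairpins only.

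The 29 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. The rule named PTK7; up to 10 genes per direction for the averaged contrast and up to 5 for each line, taken by size among those past the threshold whose PTK7 arrays both lay beyond both control arrays, and filled up by smallest unadjusted p with the same separation; the 10 largest per direction for the baseline; the 3 largest per direction between hairpins; and up to 4 members per list by unadjusted p. Values of genes used to fill up are given as values only. Other alternatives were quantile normalization, median centring, removal of the dimmest 40% of genes, the mean of a gene's probe sets, every probe set, a trended or robust prior, an additive fit, fits of a single line, and leaving out each array in turn. Cyclic loess normalization and the comparison of each PTK7 hairpin with the controls were added after seeing the data.

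The fits were tested on 10 simulated data sets per comparison, with the line means and gene spreads of these 18404 genes and 100 genes changed at each size. For the averaged contrast, 92.0% of 2-fold and 99.7% of 4-fold changes were recovered, and 5.79% of calls were false. For H1299 alone, 70.0% and 96.5% were recovered, with 5.50% false calls. For the PTK7 hairpins, 64.4% and 97.3% were recovered, with 6.02% false calls. The simulated noise was independent between arrays, without the hairpin effects that the 2 lines shared in the real data. These rates therefore do not describe the fits where such effects are present. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.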

Results

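Gene expression was measured in 2 lung adenocarcinoma lines, H1299 and H2009, after lentiviral knockdown of PTK7, which encodes a receptor tyrosine kinase-like protein of the Wnt and planar cell polarity pathways that lacks catalytic activity. Each line contributed 2 arrays with PTK7 hairpins and 2 with control hairpins. The comparisons ask which genes differ after knockdown in each line, whether the lines share these differences, and how far hairpins against the same gene differ.

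PTK7 itself, read by a single probe set (8119689), was lower in both PTK7 arrays than in both control arrays of each line. In H1299 the log2 value was 5.73 with the GFP hairpin, 6.03 with LUC, 5.63 with PTK7-1 and 5.53 with PTK7-2. In H2009 it was 6.64 with GFP, 6.86 with LUC, 5.63 with PTK7-1 and 5.94 with PTK7-2. The group means in H1299 were 5.88 ± 0.21 (SD, n = 2) under control hairpins and 5.58 ± 0.07 (SD, n = 2) under PTK7 hairpins, which leaves 81.0% of the control signal. The H1299 difference of -0.30 was -0.45 without the GFP array and -0.15 without the LUC array, and with a single probe set a weak knockdown and a compressed signal cannot be told apart. In H2009 they were 6.75 ± 0.15 (SD, n = 2) and 5.79 ± 0.22 (SD, n = 2), which leaves 51.4%. The averaged log2 difference was -0.63 ± 0.12. It did not pass the threshold over all genes (limma adjusted p = 0.190, and 0.0551 with the hairpin as a block). An exact two-sided permutation test within the lines gave p = 0.0556, the smallest value its 36 arrangements allow. These arrangements moved arrays separately in each line and leave out that the lines shared their hairpins, so this p may be too small. The difference had a standard error of 0.17 in H1299 (adjusted p = 0.804) and was -0.96 ± 0.17 in H2009 (adjusted p = 0.222), and these did not differ detectably from each other (adjusted p = 0.922).

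**Figure D1:**
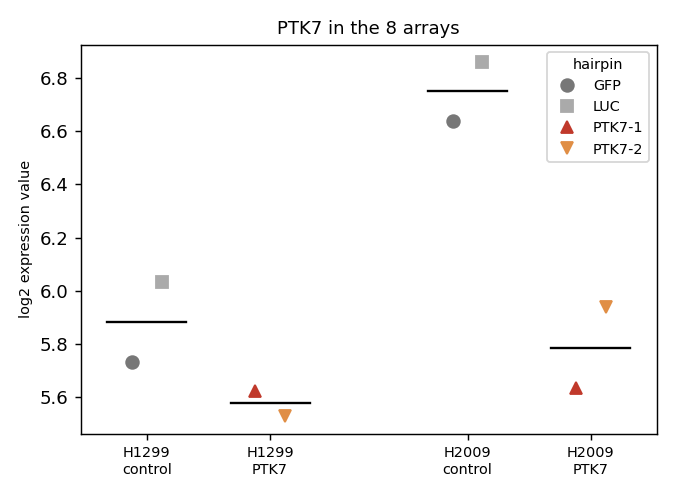
PTK7 expression (log2, vertical axis) in each array by line and group; symbols are single hairpins and bars are means of 2 arrays. Both PTK7 arrays lie below both control arrays in each line, with 5.63 and 5.53 in H1299 and 5.63 and 5.94 in H2009.

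Averaged over the lines, the desmosomal cadherin gene DSC2 and the acyltransferase gene MBOAT1 had the smallest p-values. DSC2 was 2.66-fold lower under PTK7 hairpins, with a log2 difference of -1.41 ± 0.11, and MBOAT1 was 2.73-fold lower, with -1.45 ± 0.13. The other genes named for lower values were PIK3CB at -1.32 ± 0.16, TLCD1 at -0.91 ± 0.10, SMAD1, a transducer of BMP signals, at -0.90 ± 0.10, KDM2B at -0.90 ± 0.11, COIL at -0.86 ± 0.09, DICER1, the nuclease that matures microRNAs, at -0.83 ± 0.09, MOB1B, a component of the Hippo pathway, at -0.71 ± 0.08, and INTS9 at -0.70 ± 0.08. Among genes with higher values, ANKRD1, a target of YAP and TAZ, was 4.76-fold higher at 2.25 ± 0.24, and DKK1, a secreted Wnt antagonist, was 3.41-fold higher at 1.77 ± 0.24. The oxidative stress genes HMOX1 and GCLM stood at 1.40 ± 0.19 and 0.67 ± 0.09. The rest were C3orf52 at 0.95 ± 0.11, USP53 at 0.81 ± 0.11, VTRNA1-3 at 0.76 ± 0.12, SERTAD1 at 0.74 ± 0.10, PLEKHA3 at 0.69 ± 0.11 and ABHD2 at 0.59 ± 0.08. All 20 of these genes were chosen among those with both PTK7 arrays beyond both control arrays in the same direction in each line, so this separation follows from the choice.

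None of them passed in the planned fit with a mean per group. DSC2 and MBOAT1 passed in an additive fit of line and knockdown (adjusted p = 0.0118 and 0.0161) and with a trended prior (0.0398 for both), and DSC2 passed with median centring (0.0470). The limma test with group means called 0 of 18404 genes, with a lowest adjusted p of 0.0589. In it 1819 genes had an unadjusted p under 0.05, against 920.2 by chance, a value that leaves out the hairpins shared by the lines. Mixed splits, with 1 PTK7 and 1 control hairpin on each side alike in both lines, gave 864 and 1210 such genes. Another split gave 2021, more than the real one. With the hairpin as a fixed block, 149 genes passed, 42 higher and 107 lower, and the 20 named genes were among them; with the hairpin as a random effect 0 passed. Of the 149, 48 also differed between the 2 PTK7 hairpins, among them NHP2, PIGK and ESYT1, and 0 of the 20 named genes did. The 20 were chosen by p in the fit with a mean per group, whose error includes differences between the hairpins of a group. Genes whose hairpins differ were thus disfavoured by the choice, so 0 of 20 is no evidence that the hairpins agree. In both lines together 907 genes were separated upward and 833 downward, against 511.2 per direction if arrays were arranged at random, a value that leaves out the hairpins shared by the lines. Both directions together held 1740 genes. Splits that set 1 PTK7 and 1 control hairpin against the others, alike in both lines, separated 1146 and 1301 genes, and of all 18 splits within the lines another one separated more, 2284 genes, with GFP and PTK7-2 against LUC and PTK7-1 in H1299 and the real groups in H2009. Without PTK7-1 in H1299, 5 genes passed, namely OR7E19P, COX8C, SLCO1B3, RCBTB2 and DSC2, and without PTK7-2 in H1299 only CYP1B1 passed; these names were read after their values were seen.

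**Figure D2:**
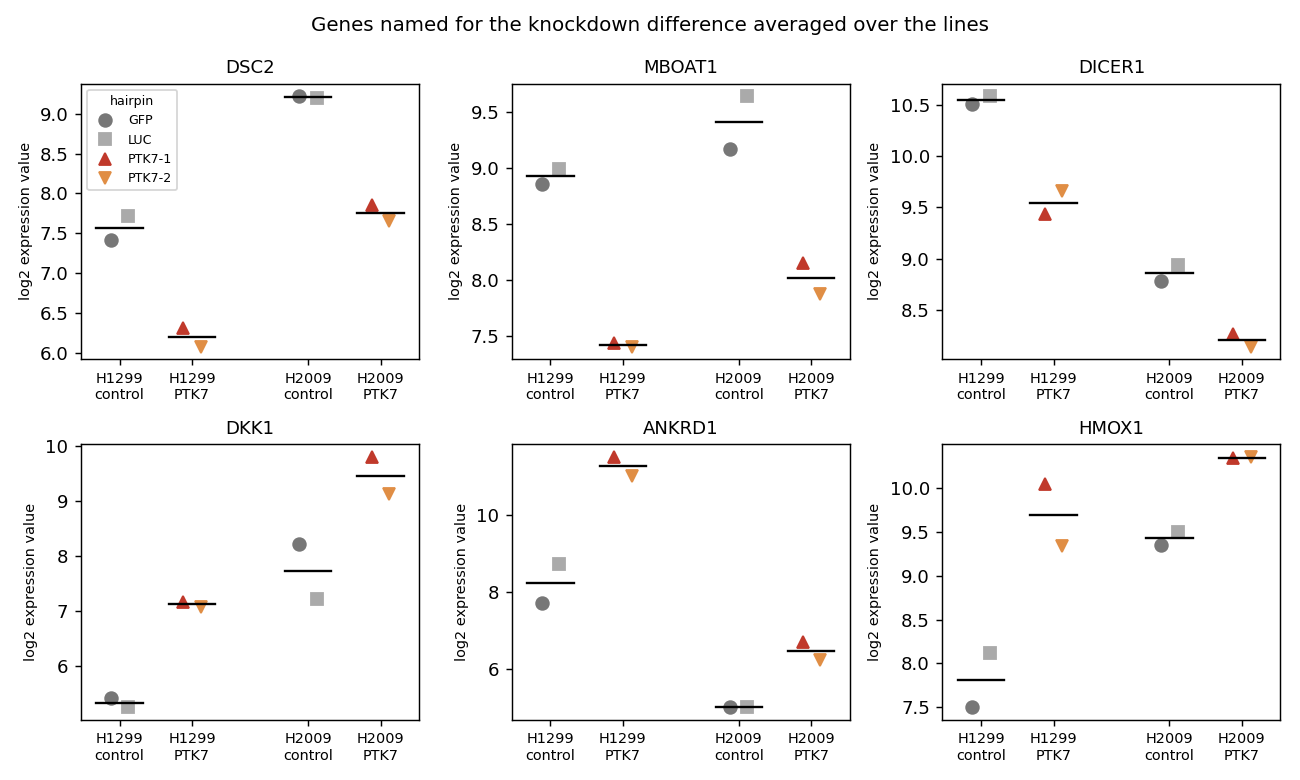
Expression of 6 named genes (log2, vertical axes) in each array by line and group; symbols are single hairpins and bars are means of 2 arrays. In every panel both PTK7 arrays lie on one side of both control arrays of the same line, by which the genes were chosen, as for DSC2, whose averaged difference was -1.41.

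In H1299, only OR7E19P, an olfactory receptor pseudogene, passed the threshold, at 3.99 ± 0.25 (adjusted p = 0.0140); its copies elsewhere in the genome make the assignment of this signal uncertain. In H2009 its difference was -0.09, and the difference between lines did not pass (adjusted p = 0.130), though it did with the hairpin as a block. The other H1299 genes are given as values. They were ANKRD1 at 3.05 ± 0.34, TMEFF2 at 1.74 ± 0.19, SERTAD1 at 1.26 ± 0.15, GCLM at 1.04 ± 0.12, HSD17B12 at -1.83 ± 0.25, MBOAT1 at -1.51 ± 0.18, DSC2 at -1.37 ± 0.16 and TLCD1 at -1.28 ± 0.13, with DICER1 also among those named. The unadjusted p was under 0.05 for 1376 genes. The blocked fit called 4 genes, OR7E19P, ANKRD1, HSD17B12 and STYX. The count was 0 without either H1299 control array or any single H2009 array, 2 without PTK7-2 in H1299, and 8 without PTK7-1 in H1299.

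In H2009, 0 genes passed in limma with or without the block, with a lowest adjusted p of 0.197 and 1468 genes at an unadjusted p under 0.05. Among the genes named for this contrast, the cytokine gene IL1A stood at 1.65 ± 0.21. FAM222A-AS1 stood at 1.16 ± 0.14, the metalloprotease gene ADAM8 at 1.16 ± 0.14, the lipase gene LIPG at 1.07 ± 0.14 and the histone gene H2AC25 at 0.94 ± 0.14. On the lower side were DSC2 at -1.45 ± 0.16, MBOAT1 at -1.39 ± 0.18, the cell cycle kinase gene WEE1 at -1.34 ± 0.17, the interferon-induced HERC5 at -1.22 ± 0.15 and ZC3HAV1L at -0.95 ± 0.12. A direct test of the difference between the lines called 0 genes without the block (951 at an unadjusted p under 0.05) and 1 with it, OR7E19P. Without PTK7-1 in H1299 it called 3, OR7E19P, SLCO1B3 and SNORD15A.

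Of the 29 gene lists, 8 passed camera in the averaged contrast, 4 toward higher and 4 toward lower values. None held with an estimated correlation or with fry, and no member of any of them passed over all genes. With the hairpin as a block, the members ANKRD1, BCL2L1, LAMB3, DICER1, AGO1 and DDX60 passed in the direction of their list. AXL, a YAP and TAZ target list member, passed in the opposite direction, at -0.72, and differed between the PTK7 hairpins (adjusted p = 0.0063). The balance of directions depended on single settings. Without the GFP array of H2009, 5 lists passed, 4 higher and 1 lower, without the PTK7-1 array of H2009 5 passed, 1 higher and 4 lower, without the dimmest 40% of genes 5 passed, 4 higher and 1 lower, and with the mean of a gene's probe sets 5 passed, 3 higher and 2 lower. Only ERK pathway output and interferon-stimulated genes passed with each of the 8 arrays left out in turn. The ERK pathway output list was higher as a group (adjusted p = 0.0012, or p = 0.511 with an estimated correlation), with 15 of 19 members higher and 3 up when adjusted over the list alone. Its mean was 0.54 in H2009, where it passed (adjusted p = 1.47e-05, or p = 0.329 with an estimated correlation), and 0.08 in H1299, with a median of -0.03, 9 members higher and 10 lower, where it did not (adjusted p = 0.706). EPHA2 stood at 0.87 ± 0.16, ETV4 at 0.88 ± 0.23 and SPRY4 at 0.74 ± 0.20. Targets of YAP and TAZ were higher (adjusted p = 0.0264, or p = 0.511 with an estimated correlation), with 16 of 19 members higher and 3 up when adjusted over the list alone, and beside ANKRD1 they included GADD45A at 0.71 ± 0.17 and AMOTL2 at 0.51 ± 0.14. This list had a mean of 0.47 in H1299, where it passed (adjusted p = 8.59e-05, or p = 0.522 with an estimated correlation), and of 0.05 in H2009, with 10 of 19 members higher (adjusted p = 1.00). Integrin and basement membrane genes were higher (adjusted p = 0.0354, or p = 0.590 with an estimated correlation), with 13 of 19 members higher and 4 up and 1 down adjusted over the list alone; LAMB3 stood at 0.86 ± 0.18, ITGB5 at 0.58 ± 0.11 and ITGB8 at -0.68 ± 0.18. Apoptosis regulators were higher (adjusted p = 0.0483, or p = 0.511 with an estimated correlation), with 17 of 22 members higher and 1 up adjusted over the list alone, and their leading member BCL2L1, at 0.90 ± 0.17, restrains apoptosis.

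Interferon-stimulated genes were lower as a group (adjusted p = 0.0012, or p = 0.590 with an estimated correlation), with 17 of 24 members lower and 1 down adjusted over the list alone. Their list mean was -0.70 in H2009, where it passed (adjusted p = 3.92e-09, or p = 0.329 with an estimated correlation), and 0.12 in H1299, where it did not (adjusted p = 0.232), with DDX60 at -2.09 and IFI44 at -1.50 in H2009. Small RNA processing genes were lower (adjusted p = 0.0264, or p = 0.511 with an estimated correlation), with 10 of 14 members lower, 4 higher and 2 down adjusted over the list alone; beside DICER1, AGO1 stood at -0.75 ± 0.24 and AGO4 at -0.57 ± 0.11. In the other direction, AGO2 stood at 0.27 ± 0.09 and TNRC6A at 0.30 ± 0.11, members read after their values were seen. AGO1 also differed between the 2 PTK7 hairpins (adjusted p = 0.0217). DNA replication genes (17 of 25 lower, 1 down adjusted over the list alone, MCM6 at -0.51 ± 0.10) and ribosomal protein genes (17 of 21 lower, 0 adjusted over the list alone) passed at the same adjusted p of 0.0483, and both gave p = 0.689 with an estimated correlation. DNA replication genes had a mean of -0.19 in H2009 and -0.0034 in H1299, and ribosomal protein genes -0.14 in H1299 and -0.0033 in H2009. Within single lines, DNA replication passed in H2009 (adjusted p = 0.0020, or p = 0.575 with an estimated correlation) and small RNA processing in H2009 (0.0198, or p = 0.329 with an estimated correlation), and ribosomal protein genes (0.0035, or p = 0.662 with an estimated correlation) and apoptosis regulators (0.0280, or p = 0.549 with an estimated correlation) in H1299. In the other line they did not pass (0.868, 0.157, 0.796 and 0.323), and integrins and basement membrane passed in neither (0.0956 in H1299 and 0.0538 in H2009). With the hairpin as a block, DNA replication and ribosomal protein genes did not pass in the averaged contrast (adjusted p = 0.0678 and 0.0699). In single lines with the block, integrins and basement membrane passed in both (adjusted p = 0.0482 in H1299 and 0.0143 in H2009). In H1299, relative to the control mean, this list stood at 0.19 with PTK7-1 and 0.24 with PTK7-2. The H1299 controls stood at 0.19 with GFP and -0.19 with LUC, so PTK7-1 was level with GFP. In H2009 it stood at 0.17 and 0.25 with the PTK7 hairpins, against 0.07 with GFP and -0.07 with LUC. Without the block and with an estimated correlation this list gave p = 0.662 and 0.575. In tests of each PTK7 hairpin alone against the controls, added after the values were seen, ERK pathway output passed with PTK7-1 (adjusted p = 0.0209) and with PTK7-2 (0.0384). Interferon-stimulated genes passed with PTK7-1 and not with PTK7-2 (0.0022 and 0.552), as did YAP and TAZ targets (0.0209 and 0.328), integrins and basement membrane (0.0213 and 0.0717), small RNA processing (0.0395 and 0.123) and DNA replication (0.0413 and 0.383). Ribosomal protein genes passed with PTK7-2 and not with PTK7-1 (0.0303 and 0.904), and apoptosis regulators with neither (0.316 with PTK7-1 and 0.0533 with PTK7-2). With an estimated correlation each of these calls was lost, at adjusted p = 0.770 with PTK7-1 and 0.803 with PTK7-2. In the direct test between the 2 PTK7 hairpins none of these 8 lists passed. Among the 21 lists that did not pass in the averaged contrast, the lowest adjusted p was 0.0541, for the unfolded protein and integrated stress response. In H2009 alone this list passed, with a mean of 0.29 and 22 of 25 members higher (adjusted p = 4.45e-04, or p = 0.329 with an estimated correlation), and in H1299 it did not, with a mean of -0.05 and a median of 0.05 (adjusted p = 0.961). Canonical Wnt targets, which include DKK1, had 0.0637. In H2009 alone this list passed, with a mean of 0.36 and 13 of 14 members higher (adjusted p = 0.0060, or p = 0.500 with an estimated correlation). Its median there was 0.23, with DKK1 at 1.75 and CCND1 at 1.03. The list was dim in the H2009 controls, at 5.67 with GFP and 5.55 with LUC, where the median gene stood at 6.33. Markers of leukocytes, fibroblasts and endothelium, which did not pass, also had 10 of 12, 9 of 13 and 9 of 12 members higher in H2009. In H1299 the Wnt target list did not pass, with 7 higher and 7 lower (adjusted p = 0.777). Mitosis genes passed in both lines in opposite directions, with a mean of 0.19 and 21 of 26 members higher in H1299 (adjusted p = 6.55e-04, or p = 0.662 with an estimated correlation) and a mean of -0.18 and 22 of 26 lower in H2009 (adjusted p = 0.0011, or p = 0.575 with an estimated correlation). In H1299, NRF2 targets passed with a mean of 0.29 and 15 of 20 higher (adjusted p = 7.28e-04, or p = 0.522 with an estimated correlation). Cholesterol synthesis passed there with a mean of -0.25 and 15 of 18 lower (adjusted p = 0.0035, or p = 0.662 with an estimated correlation). In H2009 these lists did not pass (adjusted p = 0.912 and 0.598). Relative to the H1299 control mean, cholesterol synthesis stood at -0.05 with PTK7-1 and -0.46 with PTK7-2. The controls stood at -0.25 with GFP and 0.25 with LUC, so PTK7-1 lay between them. Each PTK7 hairpin alone against the controls gave a call with PTK7-1 and not with PTK7-2 for NRF2 targets (camera adjusted p = 0.0213 and 0.887). The same held for the unfolded protein and integrated stress response (0.0209 and 0.383). With an estimated correlation both calls were lost (adjusted p = 0.770). In the direct test between the 2 PTK7 hairpins neither list passed (camera adjusted p = 0.221 for NRF2 targets and 0.370 for the stress response list). The stress response list in H2009 stood above the line's controls with both hairpins, at 0.34 with PTK7-1 and 0.24 with PTK7-2. In the averaged contrast epithelial and mesenchymal genes had adjusted p = 0.434 and 0.229. Markers of leukocytes, fibroblasts and endothelium had 0.710, 0.701 and 0.325.

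As a background, camera between the GFP and LUC hairpins called 6 lists, 3 in each direction, also with 0 under an estimated correlation. This background sets 2 arrays against 2 in the fit of hairpin plus line, and the averaged knockdown difference sets 4 against 4 in the fit of group means, so the counts and means do not compare directly. ERK pathway output was higher with GFP than with LUC by a mean of 0.21 (adjusted p = 0.0051, or p = 0.897 with an estimated correlation), against a mean of 0.31 for the averaged knockdown difference. Integrin and basement membrane genes were higher with GFP by a mean of 0.26 (adjusted p = 8.70e-04, or p = 0.582 with an estimated correlation), against 0.21 for the knockdown difference.

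**Figure D3:**
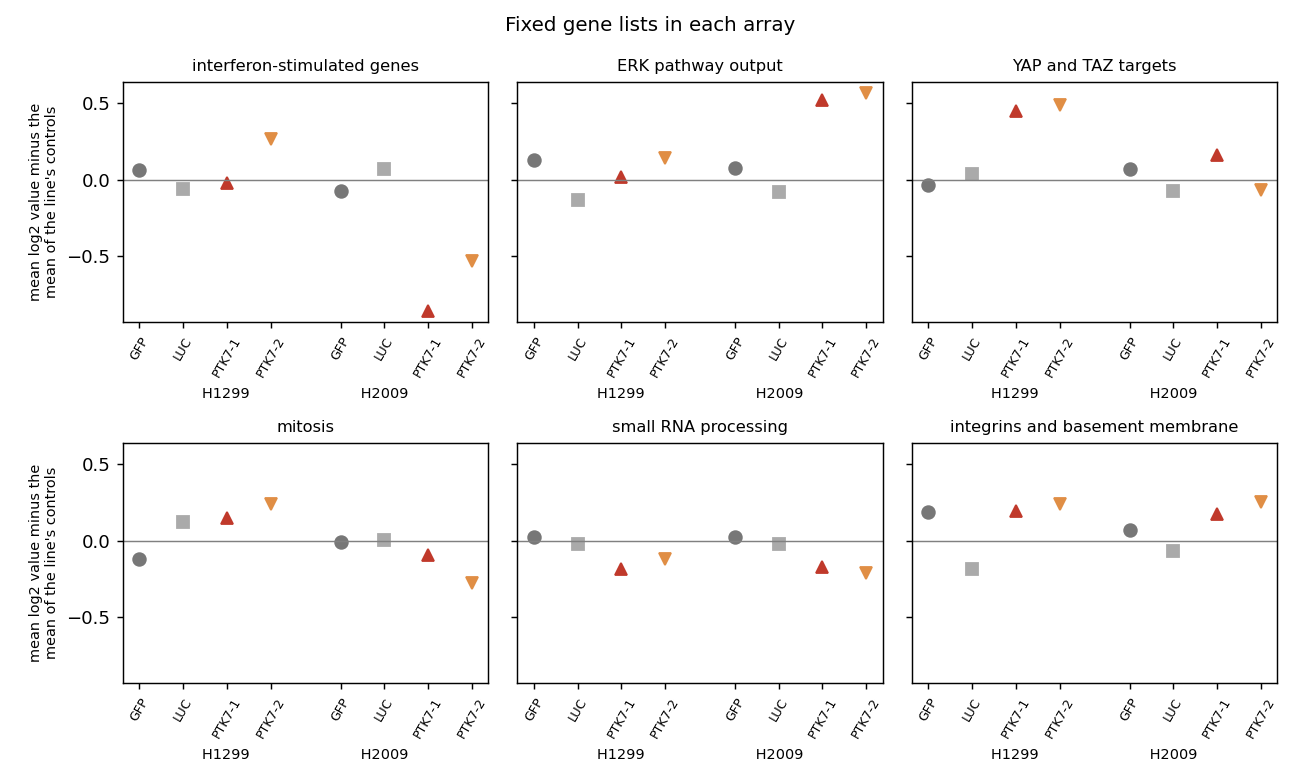
Mean of each of 6 gene lists in each array, as the log2 value minus the mean of the same line's control arrays (vertical axes), by hairpin and line (horizontal axes); each symbol is 1 array. Interferon-stimulated genes lie at -0.86 and -0.53 in the H2009 PTK7 arrays and at -0.02 and 0.27 in those of H1299.

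Across genes, the knockdown differences of the 2 lines, which share no array, had a Pearson r of 0.278 and a Spearman rho of 0.200. Without PTK7-1 in H1299, r was 0.184. Genes are not independent replicates, so no p is given. The same hairpins served in both lines. GFP minus LUC gave r = 0.230 between the lines and PTK7-1 minus PTK7-2 gave r = 0.407. When a single PTK7 hairpin was set against a single control hairpin, r lay between 0.234 and 0.390 with the same hairpins in both lines, and between -0.05 and 0.05 with different hairpins. The covariance was 0.0205 for the mean differences and averaged -2.25e-04 over the 4 pairings with no shared hairpin. At an unadjusted p under 0.05, 83 genes were higher in both lines and 165 lower, against 27.7 and 26.6 for independent lists. The values for independent lists leave out the hairpins shared by the lines. They also leave out that the tests of both lines use the same spread for each gene. Either can raise the overlap without a common effect of the knockdown.

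**Figure D4:**
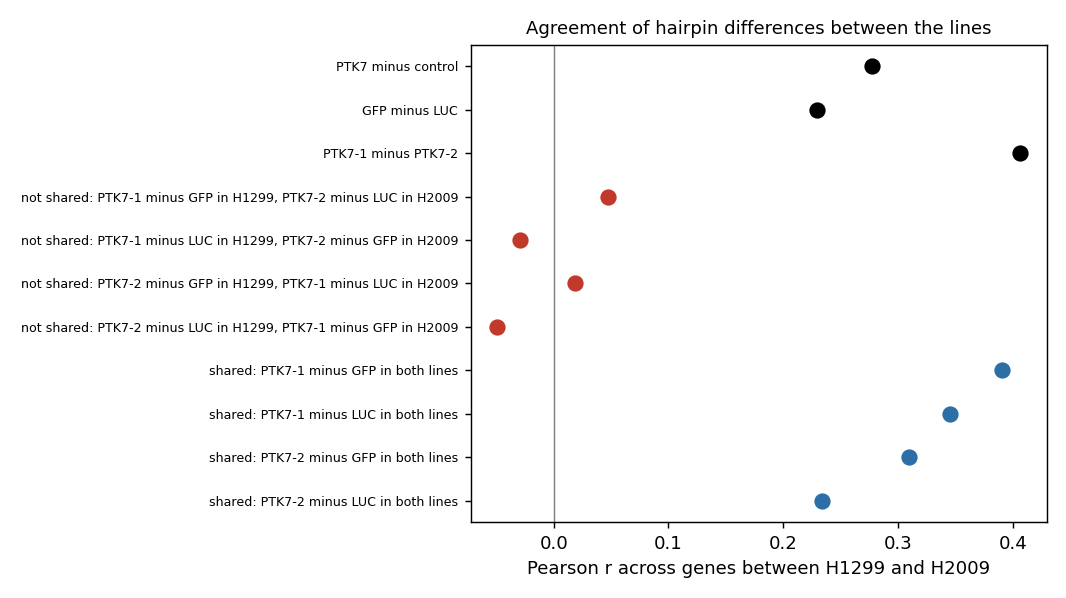
Pearson r across genes between H1299 and H2009 (horizontal axis) for each difference named on the vertical axis; black, mean of hairpins or difference within a class, red, hairpins not shared by the lines, blue, hairpins shared. The 4 red points lie between -0.05 and 0.05 and the 4 blue points between 0.234 and 0.390.

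More genes passed between the 2 PTK7 hairpins than for the averaged PTK7 minus control difference, 686 against 0, but in unlike fits. The fit of hairpin plus line takes hairpin effects shared by the lines out of the error, and the fit of group means leaves them in. With the hairpin as a block, 149 genes passed for the averaged difference, so 686 and 0 do not compare directly. Between PTK7-1 and PTK7-2, 686 genes passed, 357 higher with PTK7-1 and 329 lower, and 287 of them differed by more than 2-fold. The glycosyltransferase gene B4GALT6 was higher with PTK7-1 by 2.42 ± 0.19, the collagen chaperone gene SERPINH1 by 2.06 ± 0.20 and PPIL1 by 2.05 ± 0.21. SVIP differed by -2.12 ± 0.29, the actin regulator CFL2 by -1.84 ± 0.14 and the mitochondrial dehydrogenase gene GPD2 by -1.81 ± 0.15. PTK7 differed by -0.10 ± 0.22 (adjusted p = 0.911). Genes for NF-kB and inflammation and for oxidative phosphorylation were lower with PTK7-1 as lists (adjusted p = 0.0391 for both, or p = 0.996 with an estimated correlation). Between GFP and LUC, limma called 0 genes, with 672 at an unadjusted p under 0.05 against 3364 between the PTK7 hairpins. The count of 686 depended on single arrays. It was 0 without PTK7-1 in H1299, 97 without PTK7-2 in H1299, 92 without PTK7-1 in H2009, 943 without PTK7-2 in H2009, 301 without the GFP array of either line and 381 without the LUC array of either line. With every probe set tested it was 298.

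Under control hairpins the 2 lines differed in 4566 genes, 2296 higher in H1299 and 2270 higher in H2009, and 2408 differed by more than 2-fold. Leaving out 1 control array gave 2970 (GFP in H1299), 2910 (LUC in H1299), 2375 (GFP in H2009) and 2196 (LUC in H2009). Epithelial genes were lower in H1299, with 20 of 22 members past the threshold over all genes and 21 adjusted over the list alone, and this list also passed with an estimated correlation (adjusted p = 0.0193). The adhesion genes EPCAM and CDH1 differed by -7.85 ± 0.13 and -7.14 ± 0.13, KRT19 by -5.97 ± 0.15 and RAB25 by -6.26 ± 0.16. Other genes far lower in H1299 were MAL2 at -8.30 ± 0.17, UCA1 at -7.18 ± 0.15, TXNIP at -7.00 ± 0.14, LCP1 at -6.93 ± 0.11 and 4 small nucleolar RNA genes of the SNORD116 cluster, near-identical copies whose signals cannot be separated with certainty. Genes higher in H1299 included TDRD12 at 7.15 ± 0.15, GTSF1 at 6.98 ± 0.16, HORMAD1 at 6.56 ± 0.18 and MAGEA4 at 5.83 ± 0.22, all known for germ line expression, and also INA, PLCB4, C12orf75, IL13RA2, NRN1 and FAM9C, between 5.45 and 6.69. Mesenchymal genes went both ways, with 6 of 18 higher and 7 lower (7 and 7 adjusted over the list alone); ZEB1 stood at 3.46 ± 0.19 and FN1 at -3.29 ± 0.22.

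Interferon-stimulated genes were lower in H1299 (16 of 24 past the threshold, 17 adjusted over the list alone), with BST2 at -4.84 ± 0.14 and IFI44 at -5.24 ± 0.22. NRF2 targets had 14 of 20 lower and 2 higher, on both scales, with AKR1C3 at -2.34 ± 0.12, and integrin and basement membrane genes had 10 of 19 lower, on both scales, with ITGB6 at -5.69 ± 0.23. Hypoxia and glycolysis genes had 7 of 19 lower and 1 higher (8 and 1 adjusted over the list alone), with NDRG1 at -4.51 ± 0.30. These 4 lists and the epithelial genes were the 5 lists that passed camera, and 10 passed with the hairpin as a block. With an estimated correlation the 4 lists gave adjusted p = 0.380, 0.277, 0.380 and 0.585. With fry they gave adjusted p = 0.0023, 0.0016, 0.0023 and 0.0138, among 11 lists that fry called in this contrast. PTK7 was lower in H1299 by -0.87 ± 0.17 (adjusted p = 0.0092).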

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

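Of the tests in this part, the r between the lines for the PTK7 hairpin difference and the GFP minus LUC value of the interferon list were chosen after the results were seen, and cyclic loess normalization was added after seeing the data. The tests of unequal knockdown, of signal near the floor and of the covariance within a line were set after their patterns were seen and before their own values were.

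Gene lists that differed between the lines in the knockdown difference (H1299 minus H2009) by camera at the preset correlation were interferon-stimulated genes, with a mean of 0.82, mitosis at 0.37, YAP and TAZ targets at 0.42, ERK pathway output at -0.46, NRF2 targets at 0.28, cholesterol synthesis at -0.35, the unfolded protein and integrated stress response at -0.34, JNK pathway and AP-1 at 0.28, DNA replication at 0.18, Wnt receptors and planar cell polarity at 0.13, and ribosomal proteins at -0.14. With an estimated correlation, 0 of these 11 passed. With the hairpin as a block the Wnt receptor list no longer passed (adjusted p = 0.0829) and canonical Wnt targets did (0.0420, against 0.0643 without the block), so that 11 lists passed in each fit. The mitosis list stood at 0.14 and 0.24 above the line's controls in the H1299 PTK7 arrays and at -0.09 and -0.27 in those of H2009. The H1299 control arrays themselves stood at -0.12 with GFP and 0.12 with LUC, and the list passed between GFP and LUC (adjusted p = 0.0149, or p = 0.897 with an estimated correlation). Cholesterol synthesis, at -0.25 with GFP and 0.25 with LUC in H1299, also passed between GFP and LUC (adjusted p = 0.0021), as did ERK pathway output (0.0051) and Wnt receptors and planar cell polarity (0.0244), each with p = 0.897 with an estimated correlation. Among 13163 probe sets without a single gene name, 53 passed between the 2 PTK7 hairpins and 0 between the control hairpins.

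Interferon-stimulated genes, lower under PTK7 hairpins in H2009, had the largest mean of these list differences. A raised level in a single control array of H2009 is argued against by GFP minus LUC, which was -0.15 against a knockdown mean of -0.70. Signal near the floor in H1299 could hide a fall there, since the list was lower in H1299 under control hairpins. The 7 members brighter than the median gene in H1299 averaged 0.15 ± 0.34 (SD of the 2 hairpins) in H1299 and -0.51 ± 0.14 in H2009, and the spread between hairpins is too wide to exclude this. A response of H2009 to loss of PTK7 stays open, as does a response to the control hairpins that PTK7 hairpins lack.

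The 686 genes that differed between the PTK7 hairpins were weighed against unequal knockdown, a single aberrant array and a brightness-dependent difference between arrays. Unequal knockdown would place most of these genes farther from the controls in the same hairpin, but 55.2% were farther in PTK7-2. A single aberrant array would not repeat in the other line, but PTK7-1 minus PTK7-2 had r = 0.407 between the lines, above the 0.230 of GFP minus LUC, which argues against a single array as the whole cause. The count still fell to 0 without PTK7-1 in H1299, against 97 without PTK7-2 in H1299 and 92 and 943 without PTK7-1 and PTK7-2 in H2009, so how much of it rests on that array stays open. After cyclic loess normalization 580 of the 686 genes remained. Hairpin-specific effects, such as effects on transcripts other than PTK7, may account for the pattern, as a hypothesis that was not tested with the hairpin sequences. A batch that went with a hairpin in both lines cannot be told apart from such effects.

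The positive correlation of the knockdown differences between the lines went with the hairpins shared by both lines. The covariance averaged -2.25e-04 when no hairpin was shared, against 0.0205 for the mean differences. Effects of single hairpins would give this. A batch that went with a hairpin in both lines cannot be told apart from them, since the labels give no batch. Effects of both PTK7 hairpins that are particular to each line were looked for in the covariance of the PTK7-1 and PTK7-2 differences within a line against separate controls, which averaged 0.0147. It was 0.0275 and 0.0300 in H2009 but -0.0078 and 0.0091 in H1299, so that such effects may be present in H2009 and stay open in H1299. For the averaged contrast, the 18 ways to split the arrays within the lines are too few for a share under 0.05; the real split and the highest of the others both called 0 genes, and 18 of 18 splits called as many as the real one. At an unadjusted p under 0.05 the real split gave 1819 genes and the highest other 2021.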

How the results depend on the processing

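Cyclic loess was added after seeing the data. Genes called for the averaged knockdown difference were 0 under most settings, 1 with median centring (DSC2), 3 with a trended prior, 2 in the additive fit and 149 with the hairpin as a replicate block. For H1299 the count was 0 without the dimmest 40% of genes, 0 in a fit of its 4 arrays alone and 4 with the block. For the difference between the lines it was 1 with a trended prior, 1 with the block and 1 with the block as a random effect. The PTK7 hairpin difference gave 298 with every probe set. The correlation between the lines was 0.358 without the dimmest genes, 0.154 with every probe set, and 0.0470, -0.0291, 0.0183 and -0.0495 in the pairings with no shared hairpin. Lists called in the averaged contrast were 5 without the dimmest genes, 5 with the mean of probe sets, and 0 with an estimated correlation or fry. Leaving out each array gave 0 to 5 genes for the averaged difference, 0 to 8 in H1299, 0 to 0 in H2009, 0 to 3 for the difference between the lines, 2196 to 5298 for the baseline, 0 to 943 for the PTK7 hairpins, 0 to 0 for the control hairpins, 0.184 to 0.287 for the correlation, 5 to 10 lists, and for PTK7 -0.71 to -0.56 averaged, -0.45 to -0.15 in H1299 and -1.11 to -0.81 in H2009; a group left with 1 array is assumed to vary like the others. The cause of these changes was not tested, except that fits with fewer arrays or genes differ by construction. Of the named gene values, 4340 kept their side of the threshold, 114 lost it, 45 gained it and 0 changed direction. In the averaged and H2009 contrasts 0 genes passed in the planned fit, so there keeping a side means staying short of the threshold. Genes chosen by separated arrays cannot change direction when an array is left out. The others were chosen by size or small p, so the 0 is no evidence of robustness. The block gave 5767 genes for the baseline. Apart from the averaged difference, H1299 and the difference between the lines, given above, the block moved no count of genes by over 1.5 times. Beyond the changes given in the results, it changed no call of PTK7 or of a list in the averaged contrast. Signal over background was not used here, so dim genes such as those near the array medians are limited by noise that was not measured.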

Other observations

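The comparison of each PTK7 hairpin with the 4 control arrays was chosen after seeing the data. PTK7-1 gave 46 genes higher and 180 lower, and PTK7-2 gave 72 higher and 323 lower. Both hairpins called 6 genes higher and 17 lower, against 0.180 and 3.16 for independent lists, and 2 genes went opposite ways; part of this overlap comes from the shared controls. Higher with both were DKK1 (1.96 and 1.57), SERPINB7 (2.31 with PTK7-2), GMFB (1.33 and 1.03), C3orf52, LAMB3 and USP53. Lower with both were the RNA helicase gene MOV10 (-1.22 and -0.86), PIK3CB (-1.12 and -1.51), the histone gene H2BC12 (-1.40 and -0.79), SNX12 (-1.29 and -0.88), DSC2 and MBOAT1, with DICER1 and SMAD1 also among the 17. Across genes the differences of the 2 hairpins had r = 0.215 and a covariance of 0.0166. Simulated groups with no effect against the same controls gave r = 0.335 and a covariance of 0.0081. The simulated noise was independent between arrays, without the hairpin effects shared by the lines. The real and simulated values therefore do not compare directly. With GFP as the control of one hairpin and LUC of the other, the covariance was 0.0049 and 0.0095.

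Among the genes far lower with 1 PTK7 hairpin, the following were singled out after their values were seen. MDM2, the p53 ubiquitin ligase, stood at -1.72 relative to controls with PTK7-2 and at 0.33 with PTK7-1, nucleolin (NCL) at -1.60 and 0.20, and NHP2, a component of small nucleolar ribonucleoproteins, at -2.18 and -0.14. With PTK7-1, PIGK stood at -1.92 against -0.16 with PTK7-2, and ESYT1 at -1.86 against -0.20.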
